A study of Mus musculus with 2 samples.

How the data were processed

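Total RNA from mouse cells was extracted with a commercial kit, amplified and labelled with Cy3, and each sample was hybridised to 1 Agilent whole-genome mouse expression array, per the labels' protocols. There were 2 samples, 1 given the agent S180 and 1 given DMSO, so that there is no replicate in either group and the number of arrays limits the precision. Grouping followed the agent named in the labels.

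The scanner tables hold spot intensities on a linear scale, deposited as Agilent Feature Extraction 10.7.1.1 wrote them, the version also named in the submitters' processing notes. The processed intensity had background subtracted, was corrected for spatial and multiplicative trends across the array and carried surrogate values for dim spots, with no normalization between arrays, per the file headers. The raw mean intensity and the median local background intensity of each spot were used for an alternative, as deposited. The deposited table of both samples holds log2 values whose making is not given in the sources used here. Its values lay within 0.01 of quantile-normalised log2 processed signals, controls included, for 99.78% of 56745 probes in the S180 column and 99.74% in the DMSO column, and both columns had a median of 5.27. Each column followed its own array, so that its scale (log2, not centred) and direction were settled from the data and neither stayed unknown. It served as an alternative.

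Control spots and spots with a non-uniformity or population outlier flag were left out, which removed 120 non-control spots from the S180 array and 195 from the DMSO array. Log2 processed signals of the spots of a probe were averaged, and the array's 75th percentile over probes was subtracted. Of 56605 probes 3 lost all spots on an array. Probes were named through their accession in a RefSeq table of the mouse assembly GRCm38.p6, which is not the arrays' build and was used for names only; it matched 32992 probes and changed 1534 names. A further 520 were renamed through a unique synonym, and 23090 kept the name in the files. A gene was represented by its probe with the highest mean value. It counted as measured when that probe was well above background, by the scanner software's flag, and not saturated on both arrays. Of 37006 targets, 20751 were measured, 962 were well above background on the S180 array only, 429 on the DMSO array only and 14864 on neither. Where no probe of a gene passed on 1 array, its fold is a lower bound against the higher of that array's lowest well-above-background signal and the probe's own signal, after scaling. Probe positions are those in the files, on build mm9. Exons and untranslated regions were not annotated here.

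Differences are S180 minus DMSO on the log2 scale, counted at 2-fold in each direction. No p-value was computed, since genes are not replicates. The technical error came from 300 probes with 10 spots each, of which 279 were measured on both arrays with at least 8 kept spots. The pooled SD between spots of a probe was 0.054 (log2) on the S180 array and 0.041 on the DMSO array, and 0.067 for a difference between single spots. It covers the array only, not the culture, the RNA preparation or the labelling. For each of 36 gene lists the median difference of its measured members minus that of all measured genes was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart when it lay outside the central 99% of them, and lists with under 5 measured members have values only. The percentile describes these 2 arrays. The lists and 23 sets of cell type markers were chosen before the data were examined, for a cell and an agent of unknown kind. They overlap, with 25 genes on more than 1 list.

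Genes were named by a rule also fixed before the data were examined. It took the 13 largest differences in each direction among measured genes that were above the median on the brighter array, had no predicted, clone, locus, olfactory, vomeronasal, immunoglobulin or T cell receptor name, and differed 2-fold the same way with the main scaling, normexp correction and quantile normalization. Those conditions held for 50 higher and 5 lower genes. It further took the 4 largest bounds in each direction among genes not excluded by the same kinds of name, and the 4 members with the largest difference in each list that stood apart, and allowed members of a preset list where the list is described. A gene outside the rule is marked as chosen after its values were seen. Some list members are not reported here by name.

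Alternatives were quantile normalization, cyclic loess, the median of measured genes, no scaling, scaling on the mean of 8 Agilent spike-in transcripts, normexp background correction (offset 50), the deposited table, the mean of all measured probes of a gene, other filters on dim probes, fold thresholds of 1.5 and 3, random lists without matching, the mean of a list and wider limits. Leaving out list members shared with another list was added after seeing the data. R 4.3.3 with limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The unscaled spike-in signals differed by a mean of 0.07 (log2) between the arrays, with an SD of 0.041 over the 8 transcripts.

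The counts and percentiles were tested on simulated data for S180 against DMSO, with the levels of the 20751 measured genes, spot noise by signal group and 200 changed genes. Of 50 genes changed 3-fold and 50 changed 4-fold, all passed the 2-fold threshold, as did 49 of 50 changed 2.5-fold and 0 of 50 changed 1.5-fold. Of 20551 unchanged genes 2 passed. All 200 simulated lists of 20 genes shifted by 0.2 (log2) stood apart, as did all 200 shifted by 0.5, against 1 of 200 unshifted lists. The simulation held no difference between cultures, so that it gives no rate of false differences for the real arrays.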

Results

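The data were 2 arrays of total RNA from mouse cells, 1 from cells given an agent labelled S180 and 1 from cells given DMSO, a solvent used as the control. The labels give neither the cell type, the dose, the exposure time nor what S180 is. Each array held 62976 spots in 1 colour (Cy3). Of the 59305 spots that were not controls, 36717 (61.91%) were well above background on the S180 array and 35921 (60.57%) on the DMSO array, and no spot was saturated. Both arrays lay on the same slide and were read in the same scan. A gene was called measured when its brightest probe was well above background on both arrays, which held for 20751 of 37006 named targets. With 1 array per group, no difference below has a replicate check, and no p-value is given. The spread of replicate spots of a probe is the error used for single differences, and their number limits its precision. It leaves out disagreement between different probes of a gene. Across the 7398 genes with 2 or more measured probes, the log2 differences of the 2 brightest had a Pearson's r of 0.574. The measured genes were split by mean signal into 3 groups of equal size. A difference between single spots had an SD of 0.042 (log2) in the bright group, from 262 replicated probes. It was 0.072 in the middle group (6 probes) and 0.266 in the dim group (11 probes).

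The comparison of S180 with DMSO showed higher signals in S180 for genes that cells express when oxygen is low and for genes of glucose use. Adm, which encodes the vasodilator peptide adrenomedullin, was 4.72-fold higher in S180. Slc16a3, a transporter that exports lactate, was 4.20-fold higher, and Bnip3, a receptor for the removal of mitochondria, was 3.81-fold higher. Ak4, a mitochondrial adenylate kinase, was 5.33-fold higher on its brightest probe. Genes of cholesterol synthesis and genes of the ATF4 stress response were also higher, whereas several interferon-induced genes were lower, led by Oasl1 at 3.31-fold lower.

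Across the 20751 measured genes, 122 were at least 2-fold higher in S180 and 35 were at least 2-fold lower, together 0.76% of the measured genes. At a 1.5-fold threshold 639 genes were higher and 355 lower, and at 3-fold 24 were higher and 2 lower. Pearson's r between the arrays across genes, which are not independent replicates, was 0.9964, and the SD of the log2 differences was 0.286. In the bright group 44 genes were 2-fold higher and 0 were 2-fold lower. In the dim group 42 were higher and 28 lower. The split between the directions depended on the scaling. When the arrays were scaled on 8 spike-in transcripts, the median gene lay at -0.35 (log2), and 49 genes were 2-fold higher and 256 lower. Without scaling, 62 were higher and 173 lower.

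**Figure D1:**
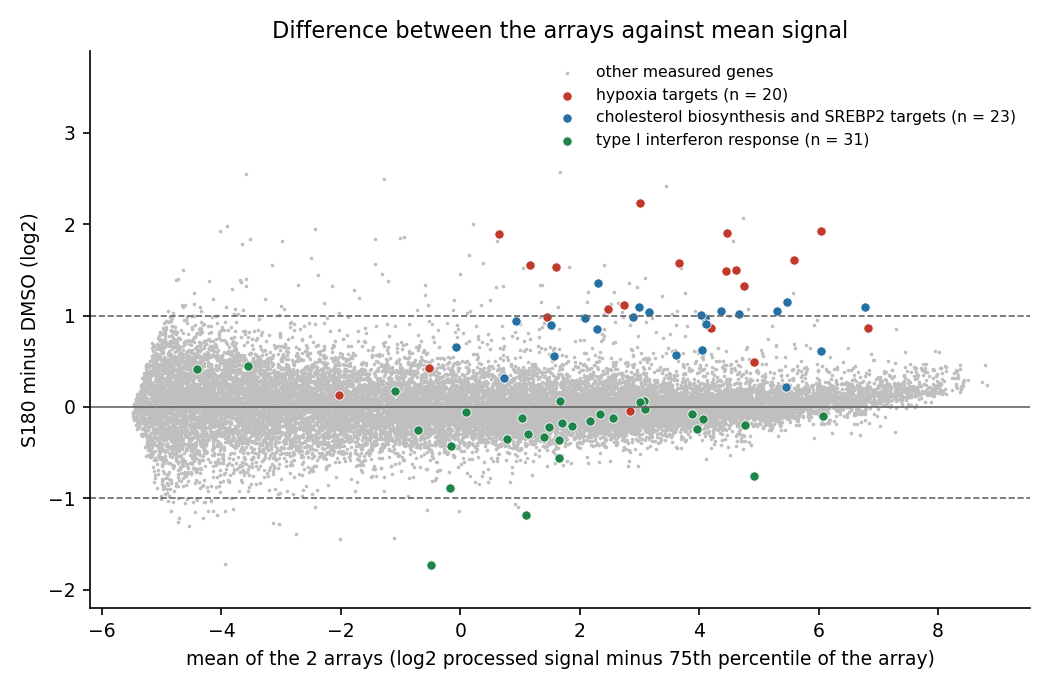
Each grey point is a measured gene, with the S180 minus DMSO difference (log2) on the vertical axis and the mean of both arrays (log2 processed signal minus the 75th percentile of the array) on the horizontal axis. Dashed lines mark 2-fold, red points are the 20 measured hypoxia targets (13 of them 2-fold higher in S180), blue points the 23 cholesterol genes (9 of them 2-fold higher), and green points the 31 interferon response genes (2 of them 2-fold lower); there is 1 array per group, and on the spike-in scale all points move down by the same amount while the medians of the red and blue points stay above 0.

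By the size rule for named genes, 13 genes were taken as higher. Kbtbd11, a kelch-repeat protein, had the largest difference, 5.93-fold higher in S180 (log2 2.57), and its pair of measured probes gave 2.57 and 2.63. Its brightest probe lies on chromosome 8 from 15033192 to 15033251 (build mm9, as all probe positions here). The Ak4 probe lies on chromosome 4 from 101139464 to 101139523, and the lower of the values of its 2 measured probes was log2 2.33. The Adm probe lies on chromosome 7 from 117773088 to 117773147, and the Slc16a3 probe on chromosome 11 from 120820023 to 120820082. Ddit4, an inhibitor of mTORC1 signalling, was 3.75-fold higher. Egln3, an oxygen-dependent prolyl hydroxylase that acts on HIF, was 3.71-fold higher, and Trib3, a stress-induced pseudokinase, 3.53-fold higher. Maff, a small Maf transcription factor, was 3.52-fold higher. Apln, the precursor of the vasoactive peptide apelin, was 3.17-fold higher, Ero1a, an oxidase of the endoplasmic reticulum, 3.04-fold higher, and Dusp8, a MAP kinase phosphatase, 2.99-fold higher. Aire, a transcriptional regulator known from the thymus, was 4.01-fold higher on its brightest probe, but another probe of Aire gave a log2 difference of 0.36. All 13 stayed higher in S180 on the spike-in scale.

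Only 5 genes met the same rule in the other direction, all of them lower in S180 under every scaling tried. Oasl1, an interferon-induced oligoadenylate synthetase-like protein, was 3.31-fold lower (log2 -1.73), with -2.02 from its other probe. Its brightest probe lies on chromosome 5 from 115387861 to 115387920. Ifit1, an interferon-induced RNA-binding protein with its probe on chromosome 19 from 34723827 to 34723886, was 2.27-fold lower. Cyp1a1, a cytochrome P450 and a classical target of the aryl hydrocarbon receptor, was 2.20-fold lower, with its probe on chromosome 9 from 57551535 to 57551594. Ankle1, a nuclease, was 2.13-fold lower, and Angptl4, an inhibitor of lipoprotein lipase, was 2.08-fold lower. Among the 44 genes with a 2-fold difference and 2 or more measured probes, all probes went the same way in 43, and by at least 1.5-fold in 33.

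**Figure D2:**
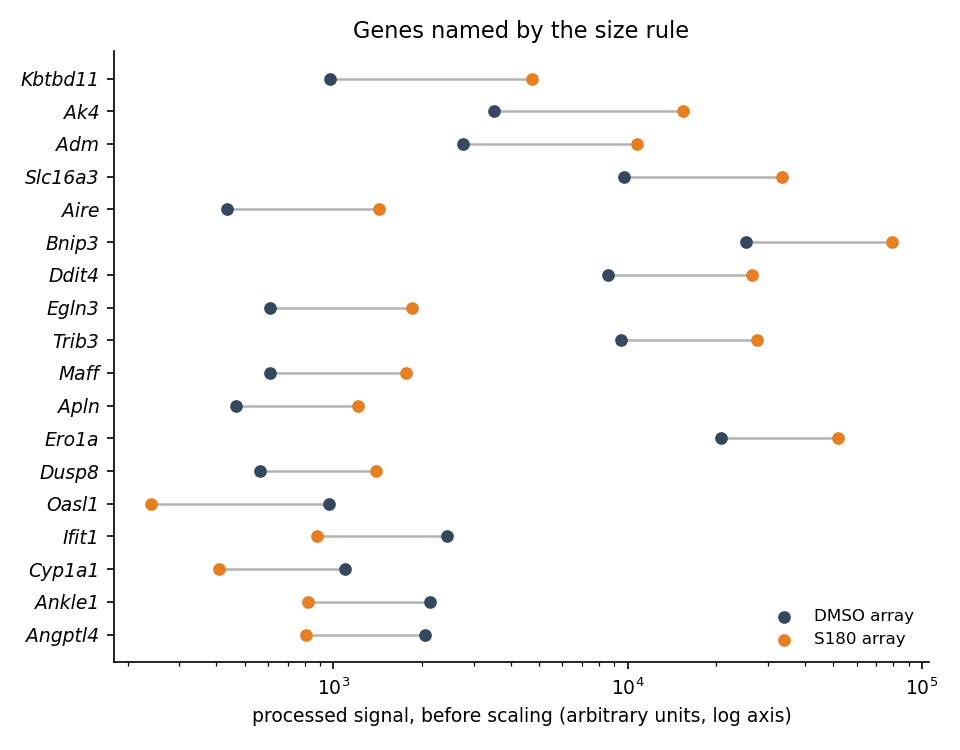
Processed signal (arbitrary units before scaling, log axis) of the 18 genes taken by the size rule, 1 gene per line, on the DMSO array (dark points) and the S180 array (orange points). The upper 13 genes were higher and the lower 5 lower in S180, as with every scaling tried; values are to be compared along a line, since levels of different probes are not comparable, and each point is 1 array.

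Some genes were well above background on a single array and have only a bound, taken against the dimmest signal well above background on the other array, or against the probe's own signal there where that was higher. There were 956 such genes on the S180 array, 54 of them at least 2-fold higher, and 422 on the DMSO array, 16 of them at least 2-fold higher there. The largest bound, at least 16.4-fold higher in DMSO, belonged to the predicted gene Gm9973 (signal 262 on the DMSO array and 7.3 on the S180 array), which the naming rule excluded by its name and which was chosen after its values were seen. Among genes whose names the rule allowed, the 4 largest bounds in each direction were as follows. Slc10a6, a transporter of sulfated steroids, was at least 3.68-fold higher in S180. The neuronal transcription factor gene Neurod2 was at least 3.12-fold higher, the neurofilament gene Nefl at least 2.72-fold and the zinc finger gene Zfp872 at least 2.49-fold. Ms4a4b, a membrane protein of T cells, was at least 2.99-fold higher in DMSO, and Spib, a transcription factor of B cells, at least 2.87-fold. Ano5, of the anoctamin family, was at least 2.03-fold higher in DMSO and Ceacam16, of the CEA-related adhesion family, at least 1.96-fold. All 8 of these had signals under 50 on the brighter array.

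Among 36 gene lists fixed beforehand, the hypoxia targets stood farthest from the median gene. Of 20 measured members 13 were at least 2-fold higher in S180, and the list's median lay 1.40 (log2) above the median gene, or 2.64-fold. It lay above all 10000 random lists matched on expression (percentile 100), whose medians had an SD of 0.044. Besides Adm, Bnip3, Ddit4 and Egln3, Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, was 2.99-fold higher, with 0.65 to 2.06 (log2) over 5 probes. Vegfa, the main angiogenic growth factor, was 2.90-fold higher (0.69 to 1.68 over 4 probes), and Egln1, the principal HIF prolyl hydroxylase, 2.5-fold higher. Car9, a carbonic anhydrase and a common marker of hypoxia, differed by a log2 value of 0.13, and Pfkfb3 by -0.04. All 18 measured glycolysis genes lay above the median gene, 4 of them by 2-fold or more, with a list shift of 0.48 (percentile 100; random SD 0.041). Of the ribosomal protein genes 29 of 30 also lay above the median gene, although that list did not stand apart. The glycolysis shift was 0.35 with quantile normalization and 0.40 with cyclic loess, and the list's median on the spike-in scale was 0.13. The glucose transporter gene Slc2a1 was 2.81-fold higher, Pfkl (phosphofructokinase) 2.55-fold and Hk2 (hexokinase) 2.37-fold.

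The genes of cholesterol biosynthesis and the SREBP2 targets lay 0.97 (log2) above the median gene, or 1.96-fold, at percentile 100 (random SD 0.040). All 23 measured members were above the median gene and 9 were 2-fold higher. Mvd, of the mevalonate pathway, was 2.56-fold higher, Hmgcs1, which makes HMG-CoA, 2.22-fold, Hsd17b7 2.14-fold and Msmo1, a sterol oxidase, 2.13-fold. Fatty acid synthesis genes lay 0.33 above the median gene at percentile 100 (random SD 0.050), with 0 of 16 members 2-fold apart. Fasn and Acly, the genes for fatty acid synthase and ATP citrate lyase, were each 1.51-fold higher, Scd2 1.42-fold and Elovl6 1.39-fold.

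Of the ATF4 and integrated stress response genes all 23 measured members lay above the median gene, 6 of them 2-fold higher, and the list shift was 0.68 (percentile 100; random SD 0.045). Ddit4 and Trib3 are named above. The transcription factor gene Atf3 was 3.64-fold higher and Chac1, which degrades glutathione, 2.66-fold. The aminoacyl-tRNA synthetases, which charge tRNAs, lay 0.14 above the median gene at percentile 99.93. Sars was 1.46-fold higher, Cars and Aars each 1.37-fold, and Nars 1.29-fold. Their shift was 0.09 with normexp. The synthetase call was lost against random lists not matched on expression (percentile 98.69).

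The immediate early genes lay 0.41 above the median gene at percentile 100, with 4 of 18 members 2-fold higher. Those were Atf3, Egr1 at 2.44-fold, Btg2 at 2.27-fold and Fos at 2.04-fold, the last 3 being early transcription regulators. On the spike-in scale Egr1, Btg2 and Fos fell short of 2-fold (log2 0.93, 0.83 and 0.67), as they did with normexp (0.997, 0.703 and 0.970). Feedback genes of the ERK pathway lay 0.39 above the median gene at percentile 100, led by Etv5 at 2.02-fold, Ccnd1 (cyclin D1) at 1.73-fold, Spry2 at 1.68-fold and Etv4 at 1.65-fold. Etv5, the 1 member that was 2-fold higher, also fell short of 2-fold on the spike-in scale (log2 0.66) and with normexp (0.94). The p53 targets lay 0.23 above the median gene at percentile 99.99, with 3 of 20 members 2-fold higher. The stress cytokine gene Gdf15 was 2.5-fold higher, the cell cycle inhibitor gene Cdkn1a 2.32-fold on its brightest probe, and Sesn2 1.83-fold. The 3 probes of Cdkn1a ranged from log2 0.33 to 1.83. The NRF2 targets lay 0.22 above the median gene at percentile 99.99, with catalase (Cat) at 2.86-fold, haem oxygenase 1 (Hmox1) at 1.86-fold, the cystine transporter gene Slc7a11 at 1.71-fold (log2 0.64 to 1.41 over 4 probes) and Osgin1 at 1.38-fold. However, Gclc and Gclm, the classical NRF2 targets of glutathione synthesis, had log2 differences of -0.26 and -0.19. The NRF2 shift was 0.12 with quantile normalization and in the deposited table, and the p53 shift 0.40 with the mean of the list.

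A further 4 lists stood apart with small or less stable shifts. The glucocorticoid targets lay 0.20 above the median gene (percentile 99.70), led by Errfi1 at 1.51-fold, Per1 at 1.44-fold, Tsc22d3 at 1.32-fold and Mt2 at 1.21-fold. The YAP targets lay 0.19 above it (percentile 99.80), led by Ccn2 at 1.71-fold, F3 at 1.42-fold, Ccn1 at 1.36-fold and Amotl1 at 1.21-fold. The actin cytoskeleton and SRF targets lay 0.19 above it (percentile 99.79), led by Zyx at 1.33-fold, Acta2 at 1.29-fold, Vcl at 1.23-fold and Tpm4 at 1.19-fold. The list of alternative macrophage activation, with 6 measured members, lay 0.32 above it (percentile 99.62), led by Egr2 at 1.99-fold, Chil3 at 1.34-fold, Tgm2 at 1.33-fold and Il4ra at 1.18-fold. Of the 12 alternatives the glucocorticoid call was lost under 9, among them quantile normalization, cyclic loess and the deposited table, the YAP call under 6, and the other 2 calls under 4 each. The wider limits were among the 12 and could not lose a call, and quantile normalization and the deposited table hold nearly the same values. The YAP shift was 0.02 in the brightest 50% of genes, the macrophage shift 0.02 with all probes and the actin shift 0.09 with the mean of the list. On the spike-in scale the medians of these 4 lists and of the fatty acid, synthetase, p53 and NRF2 lists lay between -0.21 and -0.02, so that they were higher only relative to the median gene. The medians of the ERK feedback and immediate early lists were then 0.04 and 0.06, near the spike-in SD of 0.041. On that scale the members at least 2-fold higher numbered 10 of the 13 for hypoxia, 1 of the 9 for cholesterol, 4 of the 6 for the ATF4 response, 2 of the 4 for glycolysis, 1 of the 4 for the immediate early genes and 0 of the 3 for p53.

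Lower relative to the median gene were 5 lists, with quantile normalization and cyclic loess as well. Scaling by 1 factor per array cannot change such a shift. The interferon response genes lay at -0.18 (percentile 0.01), with 25 of 31 members below the median gene and 2 of them, Oasl1 and Ifit1, 2-fold lower. Mx1, an antiviral GTPase, was 1.85-fold lower and Cxcl10, an interferon-induced chemokine, 1.69-fold lower, with log2 -1.58 from its other probe. The genes of G2 and mitosis lay at -0.20 (percentile 0), with 28 of 30 members below the median gene and none 2-fold lower. Kif23, a motor of cytokinesis, was 1.46-fold lower on its brightest probe (log2 -0.58 to 0.27 over 4 probes), Cdc20, an activator of the anaphase-promoting complex, 1.33-fold, and Hmmr and Kif11 1.31-fold each. The replication-dependent histones lay at -0.33 (percentile 0), with H1f2 1.72-fold, H1f3 1.65-fold, H1f1 1.53-fold and H2bc21 1.35-fold lower. The ribosome biogenesis genes lay at -0.11 (percentile 0.02), led by Dkc1 at 1.5-fold and Gnl3 at 1.33-fold lower, with Polr1b and Nop56 at 1.18-fold each. The targets of the aryl hydrocarbon receptor lay at -0.38 (percentile 0.02; 6 members). Besides Cyp1a1, Ahrr, the receptor's repressor, was 1.76-fold lower and Cyp1b1 1.72-fold lower, while the other 3 members, Aldh3a1, Nqo1 and Tiparp, lay above the median gene, at log2 0.02, 0.17 and 0.31. No member lay near the list's median, and without the 1 member shared with another list the shift was -0.79. The receptor call was lost with normexp background correction (percentile 1.35) and with all probes (-0.02, percentile 45.72), and the shift reversed to 0.245 in the brightest 50% of genes, which held 2 members; the ribosome biogenesis call was lost against unmatched random lists (percentile 1.29). The ribosome biogenesis shift was -0.17 with normexp, and the interferon shift -0.27 with the mean of the list.

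**Figure D3:**
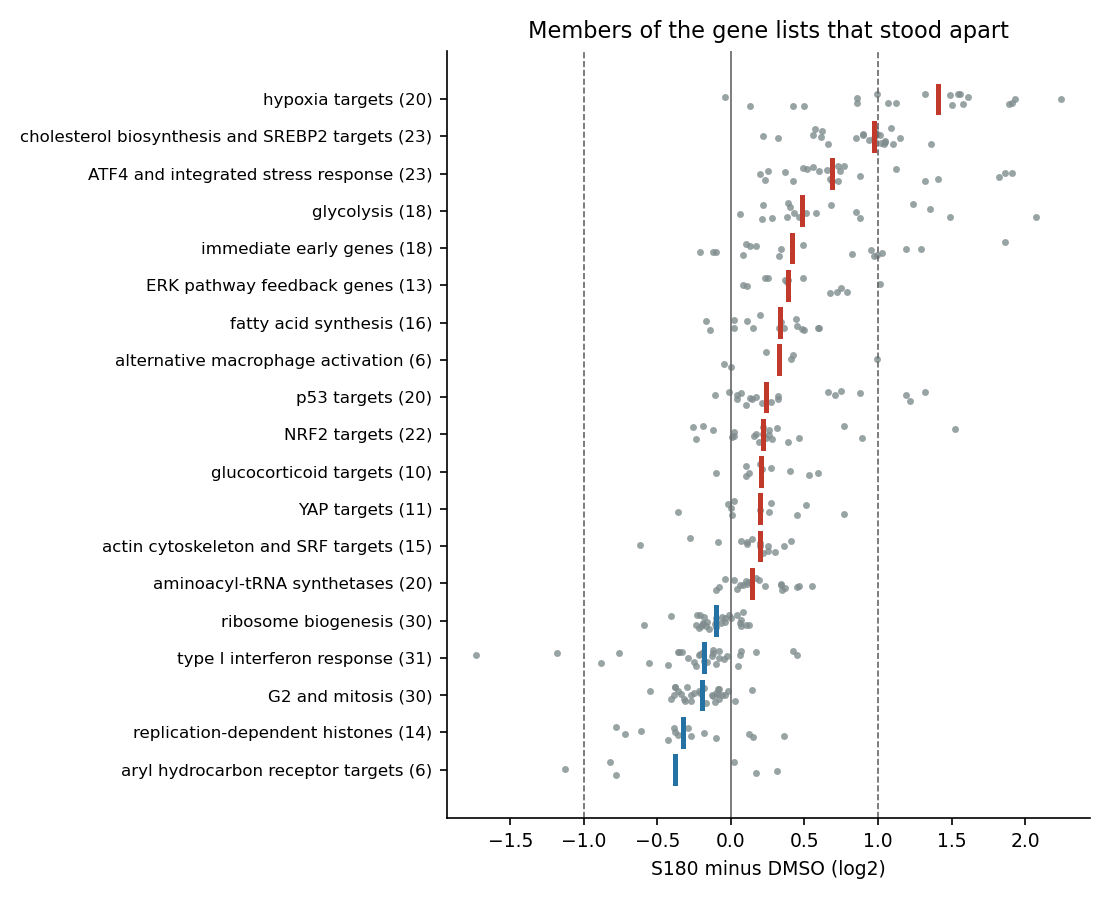
Each grey point is a measured member of 1 of the 19 lists that stood apart, with the S180 minus DMSO difference (log2) on the horizontal axis and the number of measured members in brackets. Thick bars are list medians (red higher, blue lower), dashed lines mark 2-fold, vertical scatter within a line has no meaning, and there is 1 array per group; shifts from the median gene run from -0.38 for the aryl hydrocarbon receptor targets to 1.40 for the hypoxia targets, and on the spike-in scale the medians of the 8 red lists with the smallest shifts turn from above to below 0.

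The other 17 lists did not stand apart in the main setting. Genes of oxidative phosphorylation lay 0.02 from the median gene (percentile 1.59), with none of 35 members 1.5-fold apart. The chaperones and unfolded protein response genes of the endoplasmic reticulum lay at 0.03 (percentile 35.36), with the chaperone gene Hspa5 at log2 0.09, and the heat shock genes at 0.01 (12.74). The proteasome genes lay at 0.07 (25.78), the ribosomal proteins at 0.15 (87.56), the lysosome and autophagy genes at 0.08 (86.80) and the tubulins at 0.13 (90.84). DNA replication genes lay at -0.03 (8.90). The LXR targets lay at 0.03 (64.40), and fatty acid oxidation and PPAR targets at -0.07 (10.20), although Angptl4, named above, is on that list. The NF-kappaB and cytokine genes lay at 0.13 (98.26), antigen presentation genes at -0.02 (39.58), and matrix and TGF-beta targets at 0.11 (97.57). The Wnt targets lay at -0.13 (17.09), the circadian clock genes at 0.02 (71.04), the BCL2 family at 0.16 (99.41) and the housekeeping genes at 0.12 (78.75). Without a change of the limits, 5 of these lists passed them under 1 alternative each. They were fatty acid oxidation with the mean of the list (-0.19, percentile 0.08), the ribosomal proteins against unmatched random lists (percentile 99.86), the matrix list with the mean of all probes (99.70), the NF-kappaB list with normexp (99.55) and the BCL2 family with genes well above background on at least 1 array (99.52). With the wider limits of the central 95% of random lists the NF-kappaB, matrix, BCL2 and oxidative phosphorylation lists also passed. Over the settings compared, the shift changed sign for some lists that did not stand apart. Among them were the ribosomal proteins (-0.02 to 0.18), the Wnt targets (-0.42 to 0.19) and the housekeeping genes (-0.02 to 0.14). Random lists lack the co-regulation of real pathways, so that the 19 lists that stood apart are not to be set directly against the 0.36 of 36 that random lists would give.

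Markers of cell types were used to describe which genes were well above background, and a marker counted when any of its probes was. Of all 37006 named targets, 20751 were measured on both arrays by their brightest probe. A count near that share does not set a cell type apart. The targets include predicted, clone and locus names and were judged by 1 probe each, so the share is no matched baseline for the markers. All 8 melanocyte markers were well above background on both arrays, among them Mitf, the master regulator of the lineage, and the pigment genes Tyr, Tyrp1, Dct and Pmel. Their list shift was 0.11 (percentile 68.39), with Mitf at log2 0.10 and Tyr at -0.01. On both arrays 8 of 10 pluripotency markers were well above background, with a shift of 0.25 (percentile 98.52), and 8 of 10 fibroblast markers, with a shift of -0.44 (percentile 0.01). Of the fibroblast markers Lum was 3.30-fold lower in S180, Fap 1.84-fold and Col1a2 1.77-fold, whereas Col1a1 differed by log2 -0.02, and Lum and Fap had signals under 100 on both arrays. With normexp background correction Lum lay at log2 -0.56, against -1.72 in the main setting. No sort or gate is given by the labels.

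The other 20 marker sets, with a smooth muscle share above the pluripotency and fibroblast shares, were partly above background on both arrays. For immune cells this held for 5 of 10 macrophage markers, 3 of 10 neutrophil, 4 of 8 dendritic and 4 of 8 microglia markers. It held for 5 of 10 T cell markers, 9 with a probe on the arrays, and 4 of 9 B cell markers, 8 with a probe. It held for 6 of 10 osteoclast and 5 of 9 osteoblast markers, and for 7 of 8 smooth muscle, 6 of 8 astrocyte and 4 of 8 erythroid markers. For epithelial cells it held for 4 of 10 markers, for endothelial cells for 3 of 10, and for hepatocytes for 1 of 10. Counts differed by 1 or 2 between the arrays for the mast cell, chondrocyte, adipocyte, skeletal muscle, neuron and oligodendrocyte sets, whose measured members numbered 4 of 8, 4 of 8, 4 of 10, 3 of 10, 4 of 10 and 6 of 9. Among the sets with at least 5 measured members, the shift from the median gene was -0.07 for macrophage (percentile 34.34), 0.00 for osteoclast (49.23), 0.13 for T cell (81.59), -0.23 for osteoblast (6.24), -0.12 for smooth muscle (9.04), 0.11 for astrocyte (89.73) and -0.13 for oligodendrocyte markers (6.37). With fewer members and no percentile, the shift ranged from -0.48 for epithelial markers, of which Epcam was 1.86-fold lower (log2 -0.89, but -0.05 with normexp), to 0.38 for B cell markers. It was -0.27 for erythroid, -0.20 for mast cell and -0.15 for endothelial markers. The neuron, chondrocyte, dendritic cell, skeletal muscle and neutrophil markers lay at 0.03, 0.05, 0.06, 0.07 and 0.09. The adipocyte, microglia and hepatocyte markers lay at 0.13, 0.16 and 0.19.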

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

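Pearson's r lay between 0.9964 and 0.9973, with 1 minus r within 1.5 times its main value. Counts of lists that stood apart also stayed within 1.5 times the main values. So did the 2-fold counts under quantile normalization, median scaling, cyclic loess, the deposited table and the mean of all probes. The counts of genes 2-fold higher and lower in S180, 122 and 35 in the main setting, moved elsewhere. They were 62 and 173 without scaling, 49 and 256 with spike-in scaling, 74 and 7 with normexp, 415 and 150 for genes well above background on at least 1 array, 60 and 3 in the brightest 50% of genes, and 1773 and 810 with all probes. At 1.5-fold they were 639 and 355, and at 3-fold 24 and 2. The share of higher genes, 77.7% in the main setting, ranged from 16.1% with spike-in scaling to 95.2% in the brightest 50%. The SD of the differences was 0.216 with normexp. The filters and thresholds change the number of genes counted and the scalings move every gene by a constant. The normexp offset of 50 makes the folds of dim probes smaller by arithmetic, and any other effect of normexp was not tested. Of the 19 lists, 12 stood apart under all 12 alternatives, among them leaving out shared members, which was chosen after seeing the data. The wider limits were also among the 12 and could not lose a call. Quantile normalization and the deposited table hold nearly the same values, so they are not separate checks. The receptor list reversed to 0.245 in the brightest 50%, where 2 of its members remained. Among the genes given with a value, bounds aside, those that reversed without scaling and with spike-in scaling were Aldh3a1 (-0.257 and -0.331), Amotl1 (-0.010 and -0.084), Arnt (-0.138 and -0.212), Car9 (-0.148 and -0.222), Ccng1 (-0.238 and -0.312), Epas1 (-0.279 and -0.353), Hspa5 (-0.193 and -0.267), Il4ra (-0.045 and -0.119), Mdm2 (-0.009 and -0.083), Mitf (-0.186 and -0.260), Mt2 (-0.007 and -0.081), Nqo1 (-0.109 and -0.183) and Tpm4 (-0.033 and -0.107), and with spike-in scaling alone Tiparp (-0.043) and Vcl (-0.056), all through that constant. Genes near 0 also changed sign under other alternatives, and the cause was not tested. Hspa5 and Mitf lay at -0.029 and -0.043 with quantile normalization and in the deposited table, and at -0.009 and -0.023 with the mean of all probes. Tyr lay at 0.001 with quantile normalization and in the deposited table and at 0.002 with median scaling, Col1a1 at 0.007 with cyclic loess and Epas1 at -0.038 with normexp. With the mean of all probes Hif1a lay at 0.060 and Pfkfb3 at 0.067. Of the other alternative values of these genes, 589 moved by less than the spot SD of 0.067 and 274 by more with the same sign. Without scaling and with spike-in scaling every gene moved by more than that SD, and with median scaling by less. The settings thus fixed part of this tally, which does not measure stability. No paired analysis was possible because each group has 1 array. No replicate could be left out. Signal over background limits the dim genes, where spots of the same probe spread most.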

Other observations

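Genes of glycogen metabolism and of vascular signals were grouped after the differences had been seen. Among 16 measured genes of glycogen metabolism, Gys1 (glycogen synthase), Pgm1 (phosphoglucomutase) and Pygl (glycogen phosphorylase) were 2.39-fold, 2.37-fold and 2.25-fold higher in S180, so that genes for making and for breaking glycogen were both among them. On the spike-in scale they lay at log2 0.90, 0.89 and 0.82, below 2-fold. The list as a whole lay 0.11 (log2) above the median gene at percentile 98.71, inside the limits, so that it did not stand apart, and its median on the spike-in scale was -0.24. Among 11 measured genes for secreted factors of the vascular and stromal niche, 5 were at least 2-fold higher. Adm2, a relative of adrenomedullin, was 5.62-fold higher and Stc1 (stanniocalcin) 3.60-fold, beside Adm, Apln and Vegfa. Vegfb and Vegfc lay at log2 -0.04 and -0.25. That list lay 0.80 above the median gene at percentile 100, but it was picked from genes seen to differ, so that the percentile is no evidence for the group.

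The next lists, also chosen after the data were seen, hold genes around HIF and iron. The genes for the HIF subunits differed little. Hif1a lay at log2 -0.03, Epas1 at 0.00 and Arnt at 0.14, while Vhl, whose product marks HIF for degradation, was 1.55-fold higher in S180. The list of 6 HIF subunits and regulators lay 0.05 above the median gene at percentile 81.69. The 13 measured genes of iron uptake and storage lay 0.10 above it at percentile 92.70, and neither list stood apart. Of the 157 genes 2-fold apart, 43 were on a preset response list.

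Of the tests given next, only that of iron limitation was chosen before its result was seen; the others were chosen after. The hypoxia targets were weighed against the scaling of the arrays, faults of single probes and a shortage of iron. With spike-in scaling the median of the list was 1.05 (log2), against a spike-in SD of 0.041 over the 8 transcripts. The list's median thus stayed above 0 on that scale, so that this scaling's constant was smaller than the list's difference. The SD is a spread between transcripts and leaves out an error in the amount of spike-ins added, which would move all 8 alike. Whether the spike-in scale is right was not tested. Scaling by 1 factor per array cannot change the list's distance from the median gene, so that distance was not tested. A total of 13 other probes for 8 of the 20 members had a median difference of 1.24, with all 13 above 0 (0.18 to 2.06). This argues against faults of single probes for those 8 as a set, although Pdk1 and Vegfa gave several of the 13. The other members, among them Adm, Bnip3, Ddit4 and Egln3, had 1 measured probe each and could not be checked this way. Iron limitation would be expected to stabilise HIF and the transferrin receptor transcript, and Tfrc was 0.57 higher, between the limits of 0.2 and 0.58 set for the test, with 0.72 from its other probe, so it stays open. An effect of S180 and a difference in oxygen or cell density between the 2 cultures also stay open, untested, since there is 1 array per group.

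The larger number of 2-fold higher than lower genes was weighed against noise of dim probes. In the bright group 100% of the 44 genes 2-fold apart were higher with the main scaling, which argues against noise of dim probes as the whole of it. The spike-in scale, where 49 genes were 2-fold higher and 256 lower, moves all genes by the same amount, so these counts do not test which scaling is right, and scaling as the cause stays open. A difference in the amount of labelled RNA put on the arrays could also move all genes alike. The main scaling subtracts such a constant, so that it could not make the split of 122 higher and 35 lower genes. Without scaling, the spike-in signals differed by a mean of 0.07 (log2), whereas the median gene lay at -0.28. Whether the amount of RNA relative to the spike-ins differed was not tested.

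The p53 target list shared 5 of its 20 measured members with other lists, among them the stress response. Without those the shift was 0.17 (log2) at percentile 99.86, which argues against shared members as the whole of the shift, although on the spike-in scale the full list's median was -0.12. Whether p53 was active may not be read from the list, because Mdm2 lay at 0.27 and Ccng1 at 0.04 while Cdkn1a lay at 1.22 on its brightest probe and at 0.33 on its lowest.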
